A study of Mus musculus with 6 samples.

How the data were processed

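Total RNA of isolated hippocampal cells was measured on 6 expression arrays. The sample descriptions give the cells as DGCs, which from what is known of the study are dentate granule cells, the principal neurons of the dentate gyrus. They tie the arrays to 2 control and 2 transgenic mice: mouse 1 of each group has 1 array and mouse 2 of each group has 2 arrays. The titles of 3 arrays carry the tag re-LCM, whose meaning the labels do not give: those of control mouse 1, transgenic mouse 1 and transgenic mouse 2 array 1. The last of these also carries the word block. The 2 arrays described as control mouse 2 are titled control 1 and control 2, so titles and descriptions may disagree on the mouse. No dates, sexes or ages were used.

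The deposited values are linear probe set intensities for 45101 probe sets. The authors' scaling shows in the values themselves: the 2% trimmed mean over all probe sets is 150.001 on each of the 6 arrays. The program that combined probes into probe sets, its background correction and its version are not given in the sources used here, and no scanner files were used. How background was subtracted therefore stays unknown, and it sets how far dim probe sets can be trusted. The median intensity over probe sets other than controls was 34.1, 36.8 and 36.2 on the control arrays (mouse 1, mouse 2 array 1, mouse 2 array 2) and 32.3, 35.7 and 32.4 on the transgenic arrays in the same order. The number of arrays and mice limits the precision.

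The 64 control probe sets were left out, which left 45037. In the platform annotation 34945 of these have 1 gene symbol, 932 have several and 9160 have none. Entrez identifiers matched 34741 of the single symbols to a RefSeq gene table, and this changed 0 symbols. Probe sets with several symbols or none were kept without a name. The deposited scaling was kept. Values under the pooled 25th percentile, an intensity of 10.1, were set to that floor, and log2 was taken. Between 23.9% and 26.4% of the probe sets of an array lay at or under the floor, where values have no order. Probe sets with a mean log2 value over the 6 arrays above the median of all probe sets were tested, with 1 probe set per gene, that of the highest mean. This gave 14678 tested items, of which 11138 had a gene symbol and 3540 had none. They are called genes below.

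Log2 values of the 2 arrays of a mouse were averaged, since the mouse is the replicate, and transgenic and control mice were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom and 2.70 prior degrees of freedom. Elavl4, which encodes HuD, and its relatives were also fitted with every probe set, unfiltered. There were 23 gene lists, covering the Elav family, known HuD target mRNAs, neuronal gene groups, stress and housekeeping groups and markers of the cell types that a capture from the dentate gyrus could hold. The 19 with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The tag re-LCM was tested as a term beside the group over 6 arrays. Arrays were compared by Pearson's correlation across genes, which are not independent replicates.

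Genes named in the text follow a rule. It takes the Elav family, Gap43 and Marcks. It also takes the 10 named genes per direction with the largest change past the threshold, filled up where too few pass with those of smallest p among genes that differ by at least 1 log2 unit with no overlap between the 3 control and 3 transgenic arrays. From each list it takes up to 4 members of smallest p. The text names only some of these, not always those of smallest p. Mbp, Cnp, Csf1r and Ctss were named in addition, after their values were seen, as the brightest members of 2 lists. Design, lists, naming rule and all alternatives but 1 were set before the data were examined. The alternatives changed the normalization, the floor, the filter, the treatment of several probe sets per gene, the unit of replication, array weights, the tag as a term, the mouse number as a block, the variance model and the mice or arrays included. With the mouse as a random block, lists were tested with cameraPR on the moderated t values as z scores, array weights were passed to camera, and with a variance trend camera took the trend without the robust step. A list's direction across alternatives is the sign of its median. These details of the list alternatives were chosen after the values were seen.

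The fit was tested on simulated arrays with the real means and spreads, with arrays and genes drawn independently and 200 of 14678 genes changed. It recovered 0 genes of a 2-fold change, 119 (59.5%) of a 4-fold change, 172 (86%) of an 8-fold change and 179 (89.5%) of a 16-fold change, with at most 3 false calls.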

Results

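Gene expression was compared between control mice and transgenic mice described as overexpressors of HuD, a neuronal RNA-binding protein encoded by Elavl4 that stabilises mRNAs of growing neurons. RNA of isolated hippocampal cells, dentate granule cells as far as is known of the study, was measured on 6 arrays from 2 control and 2 transgenic mice, with 3 arrays per group. Differences are given as log2 of transgenic over control, with the standard error of the limma fit on 2 against 2 mice unless stated otherwise. The granule cell genes Dsp (mean log2 12.94 in control and 12.78 in transgenic mice) and Tdo2 (8.52 and 8.10) were well above the floor in both groups.

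Elavl4 came first, as the gene that the series describes as overexpressed. Its 3 probe sets were not higher in the transgenic mice. The brightest had intensities of 122, 92.8 and 63.7 on the control arrays and 79.4, 93.3 and 60.1 on the transgenic arrays, a log2 difference of -0.33 (95% interval -1.32 to 0.66). For the second in brightness the difference was -0.15 (-1.42 to 1.11), and for the dimmest it was -0.73 (-2.43 to 0.97). None passed the limma test with n = 2 mice per group (adjusted p = 0.882, 0.990 and 0.882). Whether these probe sets match the transcript of the transgene was not examined, so the values do not check the labels. Without control mouse 1 the difference of the brightest was 0.0037, that of the second 0.25 and that of the dimmest -0.24. Within the re-LCM arrays (1 control, 2 transgenic) the brightest gave -0.50, the second -0.56 and the dimmest -1.03. Within the other arrays (2 control, 1 transgenic) the brightest gave -0.36, the second 0.40 and the dimmest -0.31.

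**Figure D1:**
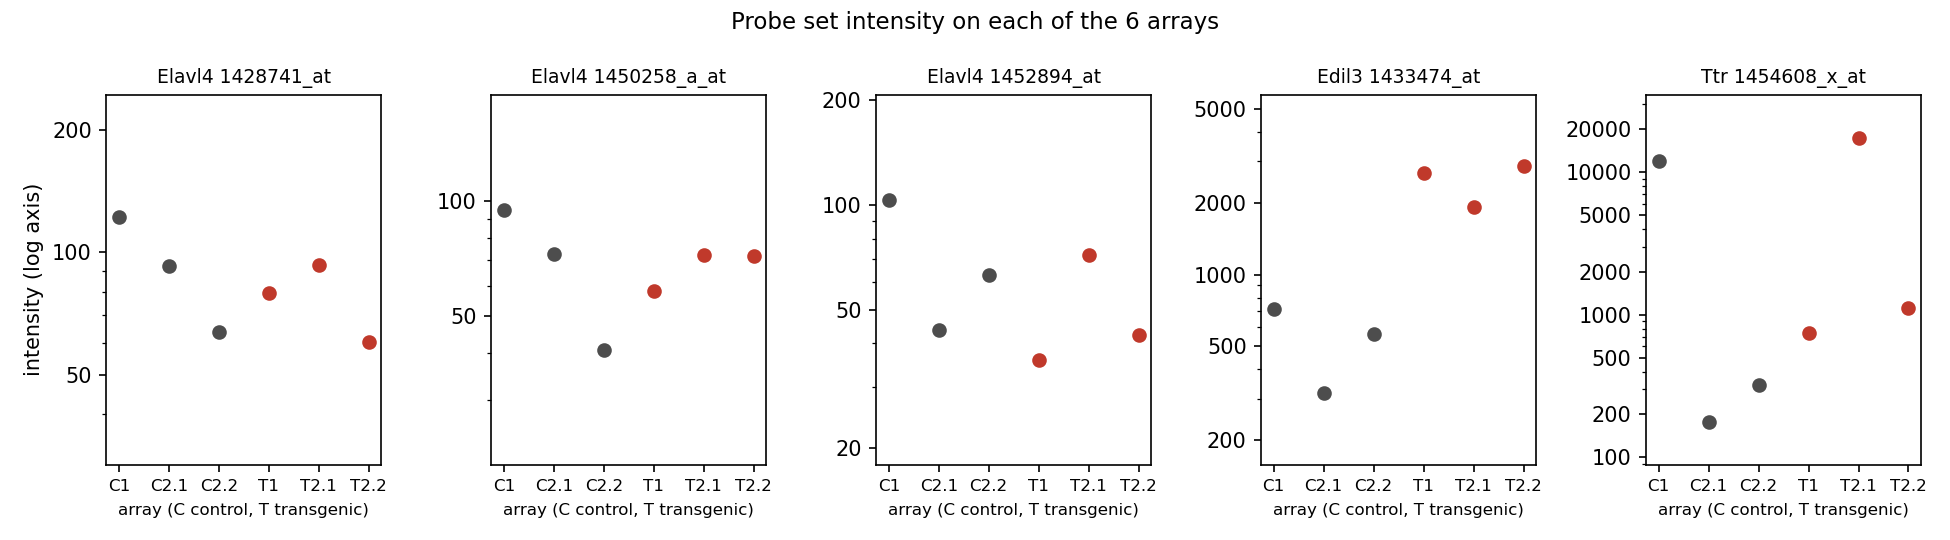
Intensity (log axis, a different range in each panel) of 3 Elavl4 probe sets and 1 probe set each of Edil3 and Ttr on the 6 arrays, with 1 point per array, control arrays (C) in grey and transgenic arrays (T) in red. Edil3 lay between 316 and 718 on the control arrays and between 1918 and 2856 on the transgenic arrays, while the Elavl4 points of both groups overlapped.

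The other Elav genes, which encode closely related RNA-binding proteins, gave differences of -0.83 (SE 0.31) for Elavl2, -0.16 (SE 0.16) for Elavl3 and 0.11 (SE 0.21) for Elavl1. Over leave-outs Elavl2 ran from -1.24 to -0.42, the last without control mouse 1. None of the 4 passed over all genes tested or adjusted over the list alone. Probe sets disagreed for Elavl3, where the remaining 2 gave 0.11 and 0.19, and for Elavl1. There a dimmer one gave -0.39, while the others gave 0.08 to 0.89, both ends from probe sets that did not pass the filter.

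The second question was which mRNAs differ between granule cells of the transgenic and the control mice. No gene passed the threshold among 14678 tested. The largest separation of a bright gene was that of Edil3, which encodes a secreted integrin-binding matrix protein. Its mean log2 intensity was 9.11 ± 0.54 in control and 11.29 ± 0.14 in transgenic mice (SD, n = 2), a 4.55-fold ratio (log2 2.19, SE 0.30). A second, much dimmer Edil3 probe set read 51.7 to 56.7 on the transgenic arrays, 33.5 on control mouse 2 array 1 and values under the floor on the other 2 control arrays, so its log2 difference of 2.01 is set by the floor. The other 4 Edil3 probe sets gave 0.10 to 0.70, with overlap, and the mean of its probe sets that passed the filter differed by 1.14. Edil3 passed only with a variance trend and robust variance (limma, adjusted p = 0.00982), against adjusted p = 0.999 without them and a range of 0.00853 to 1.00 over all alternatives.

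Among the genes leading towards higher values were Sec24b, a component of the vesicle coat that leaves the endoplasmic reticulum (1.43, SE 0.16), Zfp458 (1.70, SE 0.27), Faap100, of the Fanconi anaemia core complex (1.52, SE 0.18), Kif18b, a mitotic kinesin (1.35, SE 0.16), and Tmem215 (1.24, SE 0.15). Dclre1b (1.08), Wnt11 (1.09), Lrch4 (1.02) and Atf3, a transcription factor induced by injury and stress (1.07), completed the set. Towards lower values, Sst, the somatostatin gene of a class of interneurons, had a difference of -1.47 (SE 0.26), and Lims2 one of -1.31 (SE 0.27). Cdh22, a cadherin, had -1.21 (SE 0.15), Rasgrp3 -1.18, Nxph4 -1.17, Tom1l1 -1.16, 4930448K20Rik -1.15, A930009A15Rik -1.13, Pdzrn4 -1.03 and Ptp4a3 -1.03. Apart from Edil3 these genes were dim, with group means between log2 4.27 and 7.01 over a floor of 3.33. They came from 19 higher and 32 lower named genes that met the naming rule, and none passed the threshold. With the floor at the median intensity, 11 of the 20 moved by over 1.5 times, among them Wnt11 to 0.36, Kif18b to 0.51, Lrch4 to 0.54, Faap100 to 0.84, Ptp4a3 to -0.37, A930009A15Rik to -0.48 and Sst to -0.74.

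With limma, 0 of 14678 genes were called (smallest adjusted p = 0.999), while 632 had an unadjusted p under 0.05, 258 higher and 374 lower, where 734 would be so by chance. The 3 control and the 3 transgenic arrays did not overlap for 1185 genes (8.07%), against 10% by chance if the 6 arrays were independent, a rate that ignores that 2 arrays of each group share a mouse. Leaving out a mouse or array moved 42 of the 70 genes followed across settings, most of those named here, by over 1.5 times. In the simulation, the fit recovered 0 of 200 genes changed 2-fold and 119 of 200 changed 4-fold, so in its setting changes of 2-fold were not detected. That setting drew arrays and genes as independent, without a spread between mice, so the limit for these mice may differ.

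The HuD target mRNAs showed no common shift. Of 19 listed, 14 were measured, with 6 higher and 8 lower (median -0.05), and camera gave adjusted p = 0.847. Gap43, a growth cone protein whose mRNA HuD binds, had a difference of -0.85 (SE 0.58), with an intensity of 163 on the array of control mouse 1 and 38.5 to 71.8 on the others. Without control mouse 1 the Gap43 difference was -0.0035. Marcks, a membrane-bound actin regulator, gave -0.07 (SE 0.16) at its brightest probe set, and its 7 probe sets ranged from -1.34 to 0.24. Nova1 (0.24), Mapt (0.15) and Nrn1 (0.12) differed by less than 2 standard errors.

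For axon growth and guidance, 49 of 54 genes were measured, 18 higher and 31 lower, with 0 past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.408). Atf3 came closest (list-alone adjusted p = 0.0699, limma). Map1b, a microtubule-associated protein of growing axons, had a difference of 0.76 (SE 0.22), Sema6a 0.63 (SE 0.26) and Stmn4 0.48 (SE 0.21), with the last 2 down to 0.36 and 0.26 over leave-outs. Of the 27 presynaptic genes 13 were higher and 14 lower (adjusted p = 0.847), with Vamp2 at -0.32 and Cplx1 at 0.16. Of the 26 glutamatergic postsynaptic genes 13 were higher and 13 lower (adjusted p = 0.878), with the auxiliary AMPA receptor subunit Cacng8 at -0.57 (SE 0.15), the scaffold Shank3 at -0.36 and Gria3 at 0.31. The 8 GABA-A receptor genes split evenly, 4 higher and 4 lower (adjusted p = 0.847), with Gabrb1 at -0.12. Of the 17 potassium channel genes 12 were higher and 5 lower (adjusted p = 0.408), with Kcnip4 at 0.36 and Kcnc4 at -0.37. The median of the glutamatergic and the GABA-A list was above 0 (0.02 and 0.00042), while their mean and camera's direction were lower.

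Immediate early genes (21 measured, 8 higher, 13 lower, camera adjusted p = 0.648) included Egr1 at -0.28 and Ier2 at -1.15 (SE 0.32), the latter at -0.40 with the higher floor and -0.71 without transgenic mouse 1. Of the 16 heat shock and stress genes 12 were higher (adjusted p = 0.141), with Ddit3 at 0.27 and Hspa1a at 0.23. Of the 16 genes of neurogenesis and immature neurons 12 were lower (median -0.25, adjusted p = 0.0816), with the stem cell factor Sox2, which glia express too, at -1.02 (SE 0.38) and Neurog2 at -0.93. Without transgenic mouse 1 Sox2 was at -0.63 and Neurog2 at -0.34, and Neurog2 was at -0.51 with the higher floor. This list was called in 8 alternatives, with camera adjusted p over all alternatives of 0.00776 to 0.661, and its median ran from -0.32 to -0.13 over leave-outs, with -0.13 (adjusted p = 0.179) without transgenic mouse 1 and -0.17 (adjusted p = 0.469) without control mouse 1. Its mean level was highest on the array of control mouse 1 (0.28) and lowest on that of transgenic mouse 1 (-0.33), as were those of oligodendrocyte (0.95 and -0.57), microglia (0.30 and -0.30) and interneuron markers (0.34 and -0.29). The 46 ribosomal protein genes had 18 higher and 28 lower (median -0.02, but mean 0.0078 and camera's direction higher, adjusted p = 0.847), with Rpl19 at 0.27. Of 88 oxidative phosphorylation genes 63 were higher (adjusted p = 0.198), with Ndufb10 at 0.31 and Cox7c at -0.77 (SE 0.16). Of 35 proteasome genes 26 were higher (adjusted p = 0.198), with Psma7 at 0.27.

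Markers of other cell types gave the only called lists. Oligodendrocyte markers were lower in the transgenic mice as a set: all 10 measured genes had lower means (median -0.61), among them Sox10 at -1.19 (SE 0.40), Olig1 at -0.86, Cldn11 at -0.81 and the myelin gene Mag at -0.65. Microglia markers were lower too, in 7 of 7 measured genes (median -0.33), with Tyrobp at -0.60, Laptm5 at -0.37 and the complement gene C1qb at -0.28. At its preset correlation camera gave adjusted p = 0.0037 for each of the 2 lists. No single member passed over all genes or adjusted over the list alone. The estimated correlation between members was far above the preset one, at 0.655 for oligodendrocyte and 0.570 for microglia markers. The members of a list thus moved together, and their counts of lower genes are not independent support. The calls were lost with an estimated correlation (adjusted p = 0.661 for each), with fry (adjusted p = 0.608) and with the mouse as a random block (adjusted p = 0.506 and 0.225). The random block fit estimated a correlation of -0.54 between arrays of a mouse, so it gave mouse 1 of each group less weight than mouse 2. With limma that fit put 1770 of 14678 genes at an unadjusted p under 0.05.

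The array of control mouse 1 had the highest mean level of oligodendrocyte markers, 0.95 log2 units above the mean of the 6 arrays, while the other arrays lay between -0.57 and 0.04. Without that mouse the oligodendrocyte median was -0.16 with camera's direction turned to higher (adjusted p = 0.928), and the microglia median was -0.27 (adjusted p = 0.426). Without transgenic mouse 1 they were -0.34 (adjusted p = 0.0625) and -0.21 (adjusted p = 0.0724). Within the re-LCM arrays the medians were -1.27 for oligodendrocyte and -0.39 for microglia markers, and within the other arrays 0.19 and -0.23.

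**Figure D2:**
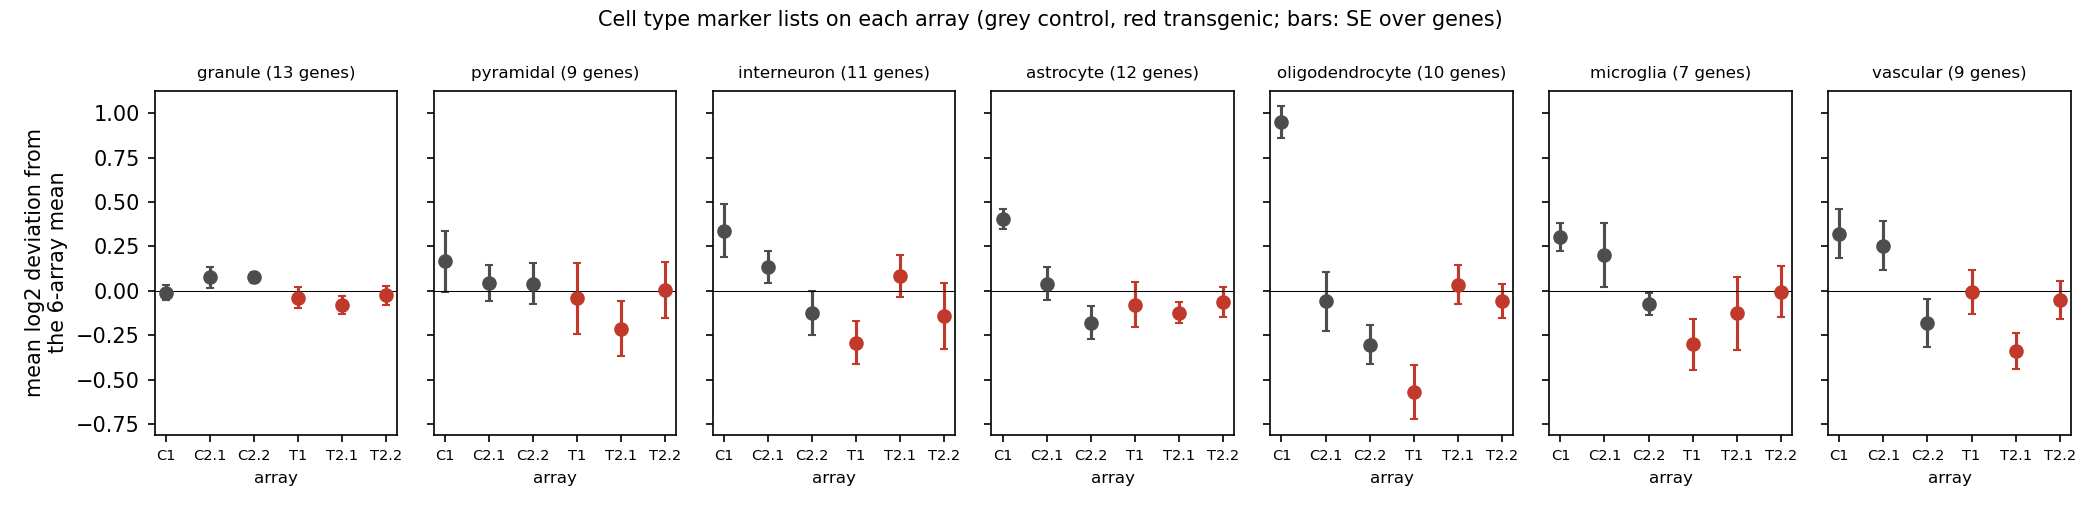
Mean log2 deviation of 7 cell type marker lists from the mean of the 6 arrays, with 1 point per array (grey control, red transgenic) and bars for the standard error over genes. The oligodendrocyte markers stood at 0.95 on the array of control mouse 1 and between -0.57 and 0.04 on the others.

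The remaining marker lists were not called. Astrocyte markers were lower in 9 of 12 (median -0.21, camera adjusted p = 0.0851), with S100b at -0.87 (SE 0.35) and Clu at -0.47, but the array of control mouse 1 stood at 0.40 and the others between -0.18 and 0.04. Without that mouse the astrocyte median was 0.04 (adjusted p = 0.928) and S100b was at -0.50. Vascular markers were lower in 7 of 9 (adjusted p = 0.103), with the tight junction gene Cldn5 at -1.15 (SE 0.34), and without control mouse 1 their median was -0.04 (adjusted p = 0.738) and Cldn5 was at -0.69. Interneuron markers were lower in 8 of 11 (median -0.36, adjusted p = 0.141), but the median was -0.05 without control mouse 1, -0.06 without transgenic mouse 1 and -0.04 with the mouse as a random block. Sst was the 1 interneuron gene to pass adjusted over the list alone (limma, adjusted p = 0.0313), with 1 transgenic array at the floor and a difference of -0.74 with the higher floor, while Cck stood at 0.35. Pyramidal cell markers were lower in 7 of 9 (adjusted p = 0.198), with Neurod6 at -0.85 and Fibcd1 at 1.02, which ran from -1.40 to -0.30 and from 0.48 to 1.56 over leave-outs. Granule cell markers were lower in 9 of 13 with a median of -0.06 (adjusted p = 0.408), Tdo2 at -0.42 and Dsp at -0.16. Too few genes were measured for a test of choroid plexus (3, median -0.05), blood (2, median -0.31) and sex-linked genes (1, -0.08). The sex-linked gene was Xist, bright in both groups at a mean log2 of 12.71 in control and 12.62 in transgenic mice. The Y-linked genes of that list were not among the tested genes.

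The tag in the array titles was compared as a possible batch. With limma 0 genes were called (smallest adjusted p = 0.937), and 754 (5.14%) had an unadjusted p under 0.05. Oxidative phosphorylation genes were higher with the tag as a set (median 0.12, camera adjusted p = 0.00102), and so were oligodendrocyte markers (median 0.45, adjusted p = 0.022). With an estimated correlation, 0.319 for oxidative phosphorylation genes and 0.566 for oligodendrocyte markers, both calls were lost (adjusted p = 0.901). For oligodendrocyte markers, tagged minus untagged arrays gave a median of 1.12 within the control group, where the 1 tagged array is that of control mouse 1, and -0.34 within the transgenic group. The call was lost without any 1 of 4 arrays, and without control mouse 1 the direction turned (adjusted p = 0.794). For oxidative phosphorylation genes the medians were -0.01 within the control and 0.27 within the transgenic group, and the call was lost without any 1 of 3 arrays (adjusted p = 0.0801 to 0.476). Among tagged arrays their mean level was 0.21 on transgenic mouse 2 array 1, but -0.0018 on control mouse 1 and 0.0026 on transgenic mouse 1. Among untagged arrays it was 0.08 on control mouse 2 array 1, and -0.16 and -0.13 on array 2 of control and transgenic mouse 2. The levels thus did not simply follow the tag. The ratio of 3' to 5' control probe sets moved with the tag as well, at 17.4, 14.8 and 19.4 for Actb with it and 22.7, 24.2 and 27.8 without.

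Arrays of the same mouse were no more alike than arrays of different mice. Pearson's r across genes had a mean of 0.961 over the 2 pairs from the same mouse, 0.965 over the 4 pairs of different mice of a group and 0.964 over the 9 pairs across groups. The closest pair joined control mouse 2 array 2 and transgenic mouse 2 array 2 (r = 0.973). These 2 arrays also had the lowest mean levels of ribosomal protein genes, at -0.15 and -0.14, against 0.16 on array 1 of the same mice. Their oxidative phosphorylation levels were the lowest too, at -0.16 and -0.13, against 0.08 and 0.21 on array 1. A technical difference between first and second arrays of a mouse was not tested. That 2 arrays of each group come from 1 mouse rests on the descriptions alone, and the titles number the 2 control arrays control 1 and control 2. With the 6 arrays taken as separate samples limma also called 0 genes, with 558 at an unadjusted p under 0.05.

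**Figure D3:**
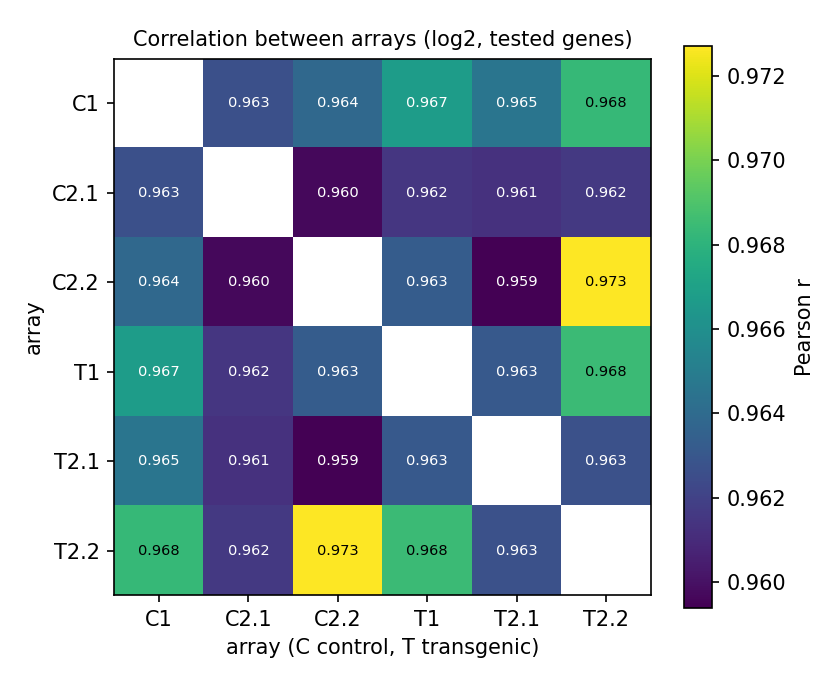
Pearson correlation of log2 intensities across the 14678 tested genes for each pair of the 6 arrays (C control, T transgenic, then mouse and array). Values ran from 0.959 to 0.973, and the 2 pairs from the same mouse did not stand above the rest.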

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

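The tests on Edil3 and on Elavl4, and the bootstrap intervals used with the marker lists, were chosen after the results were seen. Poly-A spike-in transcripts, which are bacterial RNAs added to a sample before labelling and not part of the comparison, were brighter on some transgenic arrays than on any control array. On transgenic mouse 2 array 1 the intensity was 3364 for dap, 853 for lys, 713 for phe and 848 for thr, against control maxima of 1726, 523, 436 and 448. On the array of transgenic mouse 1 dap reached 1835, while lys, phe and thr lay within the range of the control arrays. On transgenic mouse 2 array 2 all 4 were the lowest of the 6 arrays, at 1010, 249, 157 and 171, so the transgenic arrays held both the highest and the lowest values. Control mouse 2 array 2 came next above it for all 4, at 1103, 282, 182 and 226.

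The oligodendrocyte and microglia lists were lower in the transgenic mice, and their 17 measured members are in 0 other lists, though how many of them granule cells express was not measured. The brightest were Mbp and Cnp for oligodendrocytes, and Csf1r and Ctss (log2 differences -0.33 and -0.26) for microglia. Mbp read 7661 on control mouse 1, 3871 and 3010 on control mouse 2, and 3727 to 5297 on the transgenic arrays. Cnp read 3123 on control mouse 1, 1728 and 1292 on control mouse 2, and 1105 to 2301 on the transgenic arrays. Without control mouse 1 the differences were 0.31 for Mbp and -0.04 for Cnp. Csf1r and Ctss stayed lower over leave-outs, at -0.47 to -0.19 and -0.34 to -0.17. With control mouse 1 included, the 8 brighter members had a median of -0.35 (bootstrap interval -0.57 to -0.27). In that fit the lower values were thus not confined to dim probe sets. The brighter members were not tested apart without that mouse. Over all 17 members the median was -0.57. The interval resamples genes as if they were independent and holds no spread between mice. A part played by noise of dim probe sets is therefore not settled. Glial tissue taken up in single captures may account for the pattern: the mean deviation of glial markers ranged over the 3 control arrays by 2.75 times the difference between the group means of 3 arrays, and between the 2 control mice by 1.51 times the difference between the group means of 2 mice. Both ranges are set by control mouse 1, at 0.57 against 0.05 and -0.20 on the arrays of control mouse 2. They cannot tell the capture of that array from the mouse itself. The 2 arrays of transgenic mouse 2 lay close together, at -0.07 and -0.05. Still open are control mouse 1 alone, since without it the 17 members had a median of -0.27 with an interval of -0.41 to 0.19, an effect of the transgene, and chance. For chance, 10 splits of the 6 arrays, taken as separate samples, are too few. The real split called 2 lists and the highest other split 6. Of the 10 splits, 6 called at least as many lists as the real one, itself included.

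Edil3 was higher on every transgenic array. A single faulty probe set stays open: a second probe set differed by 2.01 without overlap, but it lay under the floor on 2 control arrays. An altered chromosome segment near Edil3 could not be settled, since 1 of the 16 nearest tested genes had an unadjusted p under 0.05, where 0.69 would by the rate over all genes. It was Cox7c, the tested gene directly before Edil3 in chromosome order. Cox7c differed by -0.77 and was lower on every transgenic array than on every control array. Hapln1, the tested gene directly after Edil3, gave 0.10. For chance, 10 splits of the 6 arrays are too few: the gap between the nearest arrays was 1.42 in the real split and at most 0.59 in the others among genes at least as bright, so 1 split reached it. An effect of the transgene stays open, untested.

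Elavl4 was not higher in the mice labelled transgenic. Signal too dim or too variable to show a doubling stays open: with all mice the 95% intervals of 2 of the 3 probe sets end below a log2 difference of 1 (0.66 and 0.97), but without control mouse 1 only that of the brightest does (0.40), and without either transgenic mouse 0 of 3 do. Probe sets that lie outside the transcript of the transgene could explain it; 0 of the 3 were higher on every transgenic array, which does not settle the matter without the sequences. A wrong label also stays open, and no test here bears on it.

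For the count of genes with an unadjusted p under 0.05, taken over 6 arrays as separate samples, the real split gave 558 and the highest other split 1104, with 6 of 10 splits at or above the real one. The split that follows the tag re-LCM gave 882, and with the tag as a term the group difference gave 555. These splits are too few to judge chance.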

How the results depend on the processing

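1 alternative, arrays as separate samples with trend and robust variance, was chosen after seeing the data. No gene was called under any alternative except Edil3, the 1 gene called with trend and robust variance and the 1 gene with that variance on arrays as samples. Of 1486 values of 69 named genes 16 turned direction; staying under the threshold says little where the main fit called no gene and 0 of 200 simulated 2-fold changes were recovered. Of 433 list values 356 kept direction and side of the threshold, 14 lost and 23 gained a call and 40 turned direction; the gains were 8 for neurogenesis, 6 for astrocyte, 5 for vascular, 2 for interneuron and 2 for oxidative phosphorylation genes. Keeping direction does not mean keeping size: 11 of the 20 leading genes moved by over 1.5 times with the floor at the median. The 2 called lists became 0 with an estimated correlation, 0 with fry, 0 with the mouse as a random block (estimated correlation of arrays of a mouse -0.54), 0 without a filter, 1 with a filter at the upper quartile, where neither list kept enough genes to be tested, 1 with the mean of probe sets, 5 with a floor at the median and 4 with trend and robust variance. Leaving out mice or arrays gave 0 to 6; where a group keeps 1 mouse, that mouse is assumed to vary like the others. The mouse number as a replicate block gave 0 genes and 4 lists; same-numbered mice deviated with r = 0.033, so the numbers are not shown to pair mice. The tag comparison gave 0 genes throughout. Elavl4 ran from -0.66 to 0.0037 over leave-outs, and its second brightest probe set from -0.56 to 0.25, with 0.03 on arrays as samples under either variance and 0.20 with the random block. Other values that turned direction were, for the GABA-A list, -0.018 (quantile), -0.038 (higher floor), -0.0090 (arrays as samples, either variance), -0.017 (random block), -0.0086 (array weights), -0.039 (tag as a term), -0.023 (higher filter) and -0.028 (mean of probe sets); for the glutamatergic list -0.0036 (weights), -0.032 (no filter) and -0.033 (mean of probe sets); for presynaptic genes 0.0083 (random block) and 0.010 (higher filter); for HuD targets 0.021 (random block); and for the proteasome -0.015 (tag as a term). Among genes they were Ttr at -0.0018 (quantile) and -0.25 (mean of probe sets), Mbp at 0.13 and Cnp at 0.011 (random block), and Elavl3 at 0.045 and Laptm5 at 0.084 (mean of probe sets). Over leave-outs the ranges were -0.86 to 0.31 for Mbp, -0.13 to 0.34 for Elavl1, -0.33 to 0.0056 for Dsp, -2.73 to 2.92 for Ttr and -0.013 to 0.26 for Nrn1. For lists they were -0.082 to 0.020 for HuD targets, -0.044 to 0.058 for presynaptic, -0.0997 to 0.012 for GABA-A, -0.043 to 0.043 for glutamatergic, -0.48 to 0.039 for astrocyte, -0.12 to 0.0093 for granule cell, -0.10 to 0.071 for ribosomal, -0.053 to 0.14 for oxidative phosphorylation, -0.0030 to 0.11 for proteasome, -0.19 to 0.10 for immediate early and -0.48 to 0.0017 for vascular genes. The cause was not tested for any of these. Dim probe sets near the floor limit what most leading genes can show.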

Other observations

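Ttr, which encodes transthyretin and is a main transcript of the choroid plexus, varied more between arrays than between groups. The intensity of its brightest probe set was 11996 on the array of control mouse 1 and 17436 on transgenic mouse 2 array 1, against 178 and 319 on the arrays of control mouse 2, 741 on that of transgenic mouse 1 and 1118 on transgenic mouse 2 array 2. The other 3 Ttr probe sets had their highest values on the same 2 arrays. The difference between the groups was 0.10 (SE 2.03). The brighter probe set of Sostdc1, another gene of the choroid plexus list, was 99.3 and 90.4 on those 2 arrays and between 53.6 and 89.8 on the others. The dimmer was under the floor on control mouse 1, 28.7 on transgenic mouse 2 array 1 and highest, at 40.1, on control mouse 2 array 2. The 2 Clic6 probe sets disagreed as well. The brighter Clic6 probe set read 68.0 on control mouse 1 and 56.5 on transgenic mouse 2 array 1. It had its highest values, 118 and 85.7, on control mouse 2 array 1 and transgenic mouse 1. The dimmer had its highest values, 51.4 and 41.6, on control mouse 1 and transgenic mouse 2 array 1. It read 20.6 on transgenic mouse 1 and values under the floor on the other 3. Control mouse 1 was also the array with the highest oligodendrocyte markers (0.95), while transgenic mouse 2 array 1 stood at 0.04 for these. Both arrays carry the tag re-LCM, as does that of transgenic mouse 1.

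The ratio of 3' to 5' control probe sets, a sign of RNA length after amplification, ran from 6.46 to 8.63 for Gapdh and from 14.8 to 27.8 for Actb. The Gapdh ratios were 6.92, 7.06 and 6.46 on the arrays with the tag re-LCM and 8.40, 7.87 and 8.63 on those without it, and those of Actb were 17.4, 14.8 and 19.4 against 22.7, 24.2 and 27.8.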
